A study of Mus musculus with 12 samples.

How the data were processed

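The study used J1 mouse ES cells transfected with 1000 ng of a FLAG-tagged Zscan4c expression plasmid, selected 24 h later in 500 ug/ml G418 for 10 days and picked as single clones, per the labels' protocols. Chromatin was immunoprecipitated with an anti-FLAG antibody, and libraries of about 250 bp fragments were made from 5 ng of DNA, per the same protocols. The labels describe 12 samples in 12 groups of 1: 7 from overexpressing and 5 from wild-type cells. The 10 histone mark and input samples other than the FLAG pair were not analysed here.

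The measurement analysed was 1 list of regions with start, end and score. The submitters' processing notes name cutadapt, Bowtie2, MACS2 and deepTools and the build mm10, and their versions and thresholds are not given in the sources used here. The score values were deposited by the authors as whole numbers, 1 per region and sorted from high to low, and the scale of the score is not given in the sources used here. The start and end positions were deposited by the authors in bp, counted from 0, per the file's layout, and are printed here counted from 1. The list comes from 1 immunoprecipitation, so peaks were not pooled over replicates as far as the labels say. It gives no read counts, so depth is unknown and no limit of detection was computed. Region names run from 1 to 5005, and 32 numbers in that run have no region in the list used here. Such a list holds only regions past the authors' threshold, so a gene without a listed region is not shown to be unbound.

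Genes were taken from a RefSeq table of assembly GRCm38.p6, whose primary chromosomes are those of mm10. Of 49997 genes, 49636 were used (21788 protein-coding), after leaving out 21 without a used chromosome and 340 on autosomes or the X chromosome that start below 3 Mb, where the assembly has no sequence. The table gives neither strand nor exons, and genome sequence was not used here. The planned test at transcription start sites was therefore replaced by midpoints within 1 kb of either end of a gene, and gene lists used 10 kb on either side in place of upstream only. Chromosome size was the span from the first to the last annotated or listed position, with gaps inside it kept. Scaffolds were outside these comparisons.

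Region midpoints were compared with 1000 random placements of intervals of the same widths on the same chromosomes (two-sided permutation p, smallest 0.001998). A region had a neighbour when another midpoint lay within 10 kb. Regions per chromosome were tested with a two-sided exact binomial test and Benjamini-Hochberg adjustment over 22 chromosomes. Gene lists were compared with 10000 random lists drawn from genes of every class, matched on span (the 200 nearest) and chromosome class, with adjustment over 11 lists. Scores were compared by a permutation test of the difference of medians with 100000 resamples. Intervals are 95% Wilson intervals for shares and exact Poisson intervals for rates. A dense window was 1 Mb with 10 or more regions, a limit set after the data were seen. In the closing part, symbol families of 30 or more genes were compared with 10000 rotations of the regions along each chromosome, and windows of 10 Mb were compared between chromosomes. The threshold for every call was 0.05.

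The tests, lists and alternatives were fixed before the data were examined, except for the replacements given above and where the closing part says otherwise. Alternatives were the 2510 and the 1252 regions of highest score, merging within 1 kb, autosomes and the X chromosome only, overlap of at least 1 bp in place of midpoints, windows of 5 kb at gene ends, 1 Mb at chromosome ends, 100 kb for neighbours and 50 kb for gene lists, protein-coding genes only, and Fisher's exact test for the lists. Genes were named by a rule fixed in advance, apart from the same replacements of start sites by gene ends and of upstream by either side. It named up to 4 members per list by score with a region near them, the gene at or nearest to each of the 10 highest regions, the 10 protein-coding genes with most regions, and the 10 highest regions at gene ends. Further members of a list are named where they had a region. Some list members entered the tests and are not reported here by name. The list for Zscan4 family included Zscan4a, Zscan4b, Zscan4c, Zscan4d, Zscan4e, Zscan4f. The list for 2-cell-like state included Zscan4a, Zscan4b, Zscan4c, Zscan4d, Zscan4e, Zscan4f, Zfp352, Duxf3, Dux, Duxbl1, Tcstv1, Tcstv3, Tdpoz1, Tdpoz2, Tdpoz3, Tdpoz4, Tdpoz5, Usp17la, Usp17lb, Usp17lc, Usp17ld, Usp17le, Gm4340, Gm21761, Gm8300, Gm5662, Gm2022, Gm4850, Gm6763, Gm12794, Pramef25, Pramef6, Pramel6, Pramel7, Spz1, Tmem92, Arg2, Usp26, Sp110, Zfp750, Calcoco2, Ddit4l, BC061212, Obox6, Lgals4, Ubtfl1, Rfpl4, Rfpl4b, Slc30a1, Fam46b, Nelfa, Cml2, Abcb5, Dcdc2c, Teddm3, P4ha2. The list for naive pluripotency and self-renewal included Pou5f1, Sox2, Nanog, Klf2, Klf4, Klf5, Esrrb, Tfcp2l1, Zfp42, Dppa2, Dppa3, Dppa4, Dppa5a, Tbx3, Prdm14, Sall4, Lin28a, Utf1, Fgf4, Nr5a2, Nr0b1, Tdgf1, Gdf3, Stat3, Tcl1, Mycn, Gbx2, Fbxo15, Lifr, Il6st. The list for telomere maintenance and homologous recombination included Terf1, Terf2, Terf2ip, Tinf2, Pot1a, Pot1b, Acd, Tert, Terc, Rtel1, Dkc1, Atrx, Daxx, Rif1, Blm, Wrn, Rad50, Mre11a, Mre11, Nbn, Rad52, Rad54l, Brca1, Brca2, Dmc1, Spo11, Smc1b, Rec8, Stag3, Msh4, Msh5, Hormad1, Trf1. The list for enzymes of histone acetylation, deacetylation and H3K4 methylation included Ep300, Crebbp, Kat2a, Kat2b, Kat5, Kat6a, Kat6b, Kat7, Kat8, Brd2, Hdac1, Hdac2, Hdac3, Hdac4, Hdac5, Hdac6, Hdac7, Hdac8, Hdac9, Hdac10, Hdac11, Sirt1, Kdm1a, Kdm1b, Kdm5a, Kdm5b, Rcor1, Chd4, Mbd3, Mta1, Mta2, Kmt2a, Kmt2b, Kmt2c, Kmt2d, Kdm6a. The list for DNA methylation and demethylation included Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Uhrf1, Uhrf2, Tet1, Tet2, Tet3, Tdg, Mbd2, Zfp57. The list for retroelement silencing included Trim28, Setdb1, Zfp809, Chaf1a, Chaf1b, Morc3, Sumo2, Ehmt1, Ehmt2, Suv39h1, Suv39h2, Suv39h3, Atf7ip, Resf1, Zmym2, Kdm1a, Rif1, Dppa2, Dppa4, Pias4, Tasor, Mphosph8, Pphln1, Hells, Smchd1. The list for germ layer regulators included T, Gata4, Gata6, Sox17, Foxa2, Pax6, Sox1, Nes, Eomes, Mixl1, Gsc, Hand1, Mesp1, Kdr, Neurog2, Otx2, Pax3, Tbx6, Tubb3, Afp, Sox7. The list for trophoblast and placenta included Cdx2, Eomes, Elf5, Tfap2c, Gata3, Krt8, Krt18, Hand1, Tead4, Ascl2, Esx1, Gcm1, Prl3d1, Prl2c2, Tpbpa, Krt7. The list for fibroblast markers, as another cell type a culture can hold, included Col1a1, Col1a2, Col3a1, Vim, Thy1, S100a4, Twist1, Twist2, Lum, Dcn, Postn, Fn1, Pdgfra, Pdgfrb, Acta2. The list for housekeeping genes included Actb, Gapdh, Tbp, Hprt, Ppia, B2m, Ywhaz, Sdha, Rplp0, Eef1a1, Gusb, Pgk1, Tfrc, Polr2a, Eif4a2, Psmb4. In the gene table, 3 names had no match: Dux and BC061212 in the 2-cell-like list and Suv39h3 in the retroelement list.

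Each test was checked on simulated lists of 4933 regions and 49636 genes, with 100 placements per list. A first run of 20 lists called 4 of 20 unchanged lists in the test at gene ends, more than the threshold allows, so the run was enlarged to 50 lists and a separate check of that test was added. With 50 lists, the calls among unchanged lists were 2 at gene ends, 4 in gene bodies, 2 at distal ends, 3 for neighbours, 0 for chromosomes, 3 for gene lists and 0 for scores. When 200 regions were moved, 39 of 50 lists were called in gene bodies and 50 of 50 at gene ends, at distal ends and for neighbours. In the separate check, 30 of 500 placed lists (6.00%) fell below 0.05 at gene ends against 1000 others. The unchanged lists and those of the separate check were random draws, without the clustering of the listed regions. How often the tests call lists of clustered regions was therefore not checked.

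Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.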

Results

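Zscan4c is a zinc finger protein with a SCAN domain that is transcribed in the 2-cell mouse embryo and in a small, transient fraction of embryonic stem (ES) cells, and it is known for a role in telomere maintenance. The study overexpressed it with a FLAG tag in J1 cells, a mouse ES cell line, and asked where the tagged protein sits on chromatin and which histone marks accompany it. The 12 labelled samples form 12 groups of 1: 1 FLAG immunoprecipitation, 6 immunoprecipitations of H3K27ac, H3K14ac or H3K4me1 from wild-type and overexpressing cells, and 5 inputs. The list of FLAG-Zscan4 regions from the overexpressing cells was analysed, and the histone mark libraries were not analysed here. No sample had a replicate, so the tests compared regions with placements on the genome and not cells with cells. Sequencing depth was unknown, and intervals cover counting error only.

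FLAG-Zscan4 was listed at 4973 regions that together covered 2.10 Mb of the mm10 mouse genome. Of these, 4759 lay on the 19 autosomes, 155 on the X chromosome, 13 on the Y chromosome, 6 on the mitochondrial genome and 40 on 11 unplaced scaffolds, which are assembled pieces that have no position on a chromosome. The regions were short, with a median width of 310 bp (interquartile range 248 to 479 bp, full range 219 to 4244 bp), and 192 were wider than 1000 bp. The authors' peak score had a median of 33 (interquartile range 23 to 55) and ran from 10 to 7195. A score of 100 or more was held by 549 regions (11%), and the 10 most frequent scores were shared by 46.9% of the regions. The score is the authors' value per region on a scale that the sources used here do not give, and it served only to rank and filter regions within this list.

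The first question was which regions had the highest scores. No input values and no list of artefact-prone sites were applied here, so a high score does not by itself show strong binding. The 3 regions of highest score lay on the unplaced scaffold JH584304.1, at positions 99925 to 101471 (score 7195), 109947 to 112492 (6312) and 84729 to 87240 (6020). Next came a region at the start of the assembled sequence of chromosome 9 (3023548 to 3024581, score 4515), where the nearest gene was the microRNA gene Mir101c at 14.6 kb, and a region on chromosome 6 (47753429 to 47754457, score 4410) at 1.32 kb from the long non-coding RNA gene Gm52862. The sixth region lay on chromosome 12 (120028685 to 120029001, score 3658), at 7.60 kb from Tmem196, the last annotated gene of that chromosome. The remaining 4 of the first 10 were further regions of JH584304.1 (scores 3628 and 2922), of the start of chromosome 9 (3019855 to 3021140, score 3513) and of the end of chromosome 14 (124801579 to 124802200, score 2818), where Fgf14, a member of the fibroblast growth factor family, was the nearest gene at 124 kb. None of the 5 that lay on chromosomes was inside an annotated gene.

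Among the 50 regions of highest score, 16 were on unplaced scaffolds, against 40 of all 4973 regions (Fisher's exact test, two-sided, p = 4.06e-23, adjusted p = 8.11e-23 over 4 features chosen after the scores were seen). JH584304.1 held 15 of the 50 and 26 regions in all, with a median score of 859. Those 15 lay close together on a single scaffold, while Fisher's exact test counts them as independent. The p-value therefore says little about scaffolds in general. All 6 regions in the first 100 kb of assembled sequence on chromosome 9, between 3009288 and 3024581, were among the 50 as well, with scores from 740 to 4515. The rule for naming genes did not reach the regions that follow, which were chosen after their values were seen. Asic4, a member of the acid-sensing ion channel family, held a region of score 1543 in its body (chromosome 1, 75460562 to 75462228). Trappc9 held one of score 1314 (chromosome 15, 72783128 to 72783666), Mepe one of 1176 (chromosome 5, 104330747 to 104332496), and Smo, the Hedgehog signal transducer, one of 711 (chromosome 6, 29747872 to 29748729).

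**Figure D1:**
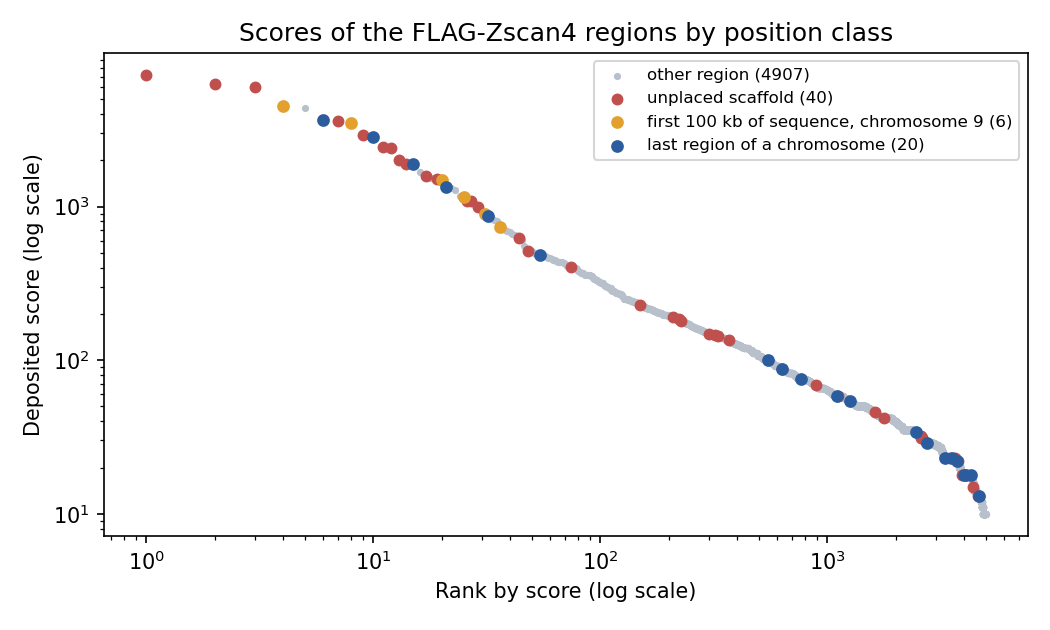
Deposited score of each of the 4973 FLAG-Zscan4 regions (vertical axis, log scale, no unit) against its rank by score (horizontal axis, log scale), with 1 point per region coloured by position class. The regions of unplaced scaffolds include the 3 highest scores (7195, 6312 and 6020), and the last regions of chromosomes 12 and 14 stand at 3658 and 2818.

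The second question was whether FLAG-Zscan4 regions followed the size of the chromosomes. Chromosome 8 carried 461 regions, or 3.65 per Mb (95% exact Poisson interval 3.33 to 4.0), which was 1.97 times its share by size (exact binomial test, adjusted p = 1.41e-40). Chromosome 1 carried 489, or 2.54 per Mb (2.32 to 2.78), 1.37 times its share (exact binomial test, adjusted p = 1.65e-11). The X chromosome had 155, or 0.924 per Mb (0.784 to 1.08), 0.498 times its share (exact binomial test, adjusted p = 9.63e-23), and the Y chromosome had 13, or 0.143 per Mb (exact binomial test, adjusted p = 5.03e-54). The other 17 autosomes lay between 1.54 and 2.09 regions per Mb with a median of 1.79, and none of them departed from its share after adjustment over the 22 chromosomes. Against that median the ratio was 2.04 for chromosome 8, 1.42 for chromosome 1 and 0.515 for the X chromosome. The mitochondrial genome also departed from its share, with 6 regions (exact binomial test, adjusted p = 4.06e-12). A share by size assumes equal copy number and equal read mapping. Neither was measured, so the departures of the mitochondrial genome and the sex chromosomes cannot be read as preference or avoidance by FLAG-Zscan4. Regions on the X chromosome were wider, with a median of 541 bp against 293 bp on chromosome 8 and 291 bp on chromosome 1, a difference that was not tested. The set of chromosomes depended on the score. With the 2510 regions of highest score 9 departed, chromosome 14 above its share and chromosomes 15, 18 and 19 below theirs in addition. With the 1252 highest 8 did, among them chromosomes 4 and 14 above and 10 and 19 below. With these 1252 regions the ratio of chromosome 1 to the other autosomes was 1.28 and no longer passed the exact binomial test (adjusted p = 0.199). That of the X chromosome was 0.819 (exact binomial test, adjusted p = 0.0456). The exact binomial test counts regions as independent, while neighbours within 10 kb were 3.66 times the number expected from placement. Its p-values can therefore be too small, and a local cluster can carry a call. Dense windows lay at 3 to 6 Mb on chromosome 14 and at 145 to 148 Mb on chromosome 4. The calls for chromosomes 4 and 14 were not tested without them. In the whole list, chromosomes 1, 8 and X still departed without dense windows.

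**Figure D2:**
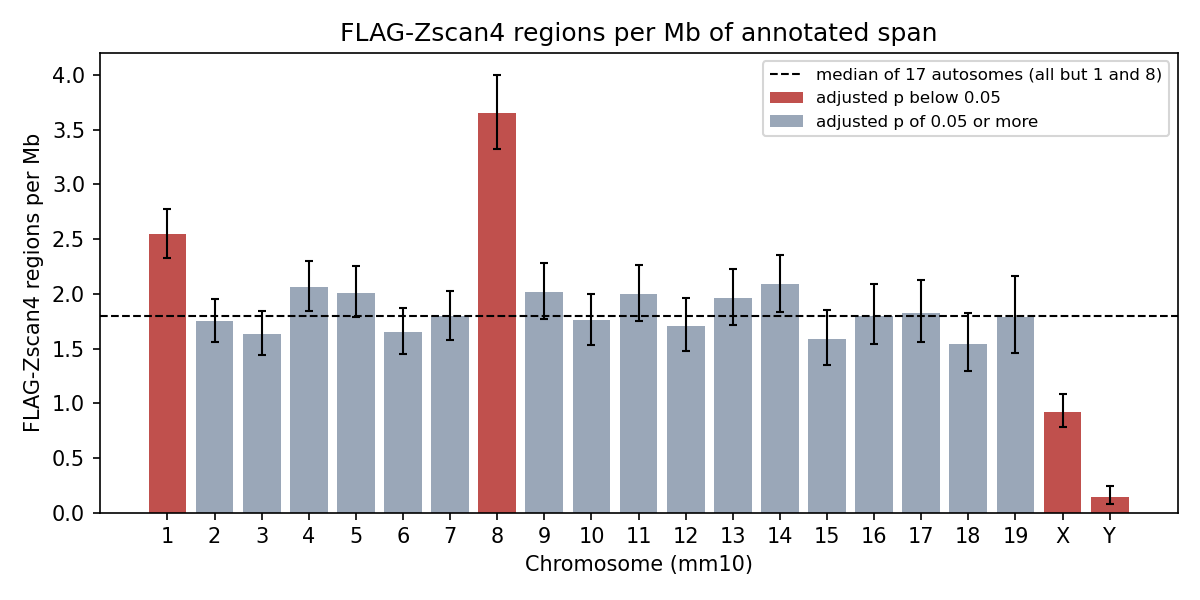
FLAG-Zscan4 regions per Mb of annotated span (vertical axis) on each chromosome (horizontal axis), with bars for the rate, whiskers for the 95% exact Poisson interval and a dashed line at the median of the 17 autosomes other than 1 and 8. Chromosome 8 stands at 3.65 and chromosome 1 at 2.54 above the line at 1.79, and the X chromosome stands at 0.924 below it, while the mitochondrial genome is left out because of its small size.

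The regions were unevenly spread within chromosomes. Of the 4927 regions on nuclear chromosomes, 720 (14.6%, 95% Wilson interval 13.7 to 15.6%) had a neighbour within 10 kb, against 197 expected from placement, a ratio of 3.66 (two-sided permutation p = 0.001998, the smallest that 1000 placements can give). The ratio was 10.9 among the 1252 regions of highest score and 1.44 when neighbours within 100 kb counted, each with the same permutation p. On autosomes and the X chromosome, 19 windows of 1 Mb held 10 or more regions and 313 regions together (6.37%). The median was 2 over all windows that held any region, the dense ones included. The densest lay on chromosome 8 between 20 and 21 Mb, with 76 regions of median score 105, and 14 of its 25 genes were pseudogenes. Beside it, a window from 19 to 20 Mb with 14 regions holds the beta-defensin genes Defb3, Defb4 and Defb14, which encode antimicrobial peptides. In the family scan of the closing part, 4 of 43 Defb genes had a region against 2.56 expected, which did not pass (permutation p = 0.547). On chromosome 4, the 3 windows from 145 to 148 Mb held 10, 17 and 23 regions among zinc finger genes such as Zfp993, Zfp978 and Zfp982. The start of chromosome 14, from 3 to 6 Mb, held 11, 15 and 21 regions among predicted genes of the Gm series.

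**Figure D3:**
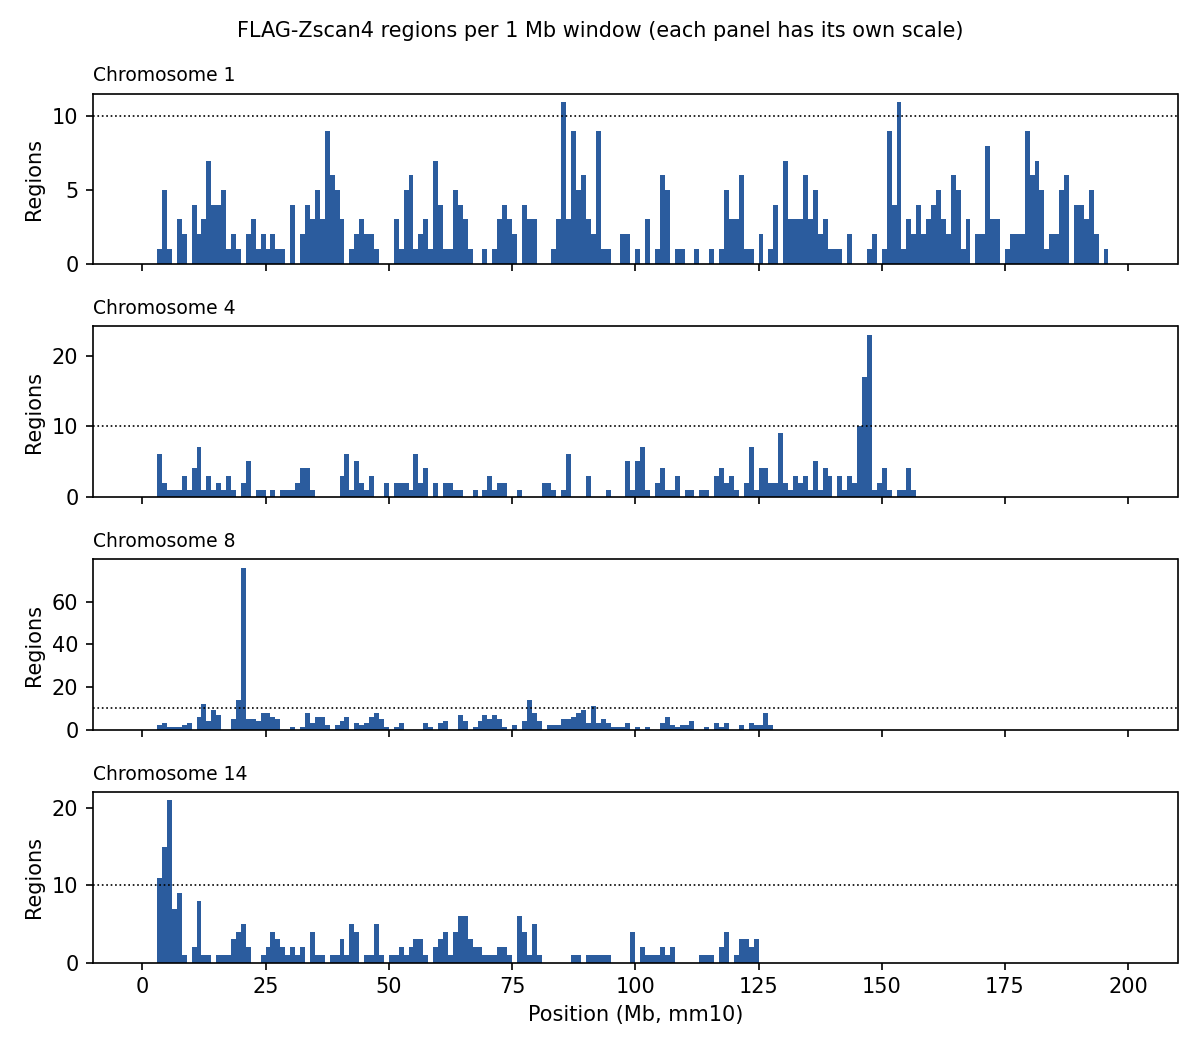
Number of FLAG-Zscan4 regions (vertical axis, a separate scale per panel) in each 1 Mb window along chromosomes 1, 4, 8 and 14 (horizontal axis, position in Mb on mm10), with a dotted line at 10 regions. A window of 76 regions stands at 20 to 21 Mb on chromosome 8, and groups of dense windows stand at 145 to 148 Mb on chromosome 4 and at 3 to 6 Mb on chromosome 14.

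The protein-coding genes with the most FLAG-Zscan4 regions in their bodies were picked by that number, so each stood above the rate of its chromosome by choice. Ulk4, a gene of the Unc-51-like kinase family, had 12 regions over 322 kb (chromosome 9, 120964454 to 121286159), against 0.649 at the rate of its chromosome. Fto, the RNA demethylase gene linked to body mass, had 9 over 355 kb (chromosome 8, 91313367 to 91668433) against 1.30, and Zfp993 had 8 over 479 kb (chromosome 4, 146512849 to 146991471) against 0.987. Gm26650, Zfp704, Zfp978, Dlgap2 and Fhit had 6 each, and Gm21119 and 4930467E23Rik had 5 each. Of these, Fhit, which spans a common fragile site, is the longest at 1612 kb and stood closest to its expected number of 3.36. In all, 1677 protein-coding genes (7.70%) had a region in the body, and 12 had 5 or more.

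The third question was where the regions lay relative to genes. Gene bodies held the midpoints of 2564 of 4933 regions (52.0%, 95% Wilson interval 50.6 to 53.4%), against 2404 expected from placement, a ratio of 1.07 (two-sided permutation p = 0.001998). Placements could fall in assembly gaps, where no region can be listed, which can lower the number expected in genes and at their ends. How much of this small excess that accounts for was not tested. Each region was given 1 class, in the order protein-coding, long non-coding RNA, pseudogene and other. A class therefore leaves out regions that also lay in a gene of an earlier class. By that order, protein-coding genes held 2072 regions (42.0%), long non-coding RNA genes a further 375 (7.60%), pseudogenes 93 (1.89%) and other genes 24, and 2369 (48.0%) lay in no gene. Exons, introns and untranslated regions were not analysed here. The excess in gene bodies was 1.00 among the 1252 regions of highest score, and this ended the call (permutation p = 0.931).

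The ends of genes, where promoters and polyadenylation sites lie, held a small share of the regions, slightly above that expected from placement in the main setting. Within 1 kb of an annotated gene end lay 352 regions (7.14%, 95% Wilson interval 6.45 to 7.89%), against 315 expected, a ratio of 1.12 (two-sided permutation p = 0.03596). This call depended on the setting: within 5 kb of a gene end the ratio was 1.23 (permutation p = 0.001998), at the ends of protein-coding genes it was 0.851 (permutation p = 0.0639), and without the dense 1 Mb windows it was 1.06 (permutation p = 0.316). The 10 highest scores at gene ends were at Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123461892 to 123462111, score 801), at the long non-coding RNA genes Gm46074 (694), Gm52873 (645), Gm40034 (476), 4930596I21Rik (352) and Gm33862 (273), at the pseudogene Gm21112 (317), at the predicted coding gene Gm40469 (283) and at the mitochondrial genes mt-Rnr2 (344) and ND4 (240). Gm46074, Gm21112 and Gm40469 lie in the dense window of chromosome 8. The mitochondrial genome holds 37 genes over 0.0154 Mb, so a place within 1 kb of a gene end says little there. Over the whole list, the score did not differ detectably between regions inside and outside gene bodies, with medians of 32 and 34 (two-sided permutation p = 0.255, adjusted p = 0.51 over 2 features), nor between those at gene ends and elsewhere, with medians of 34 and 33 (permutation p = 0.795). Among the 2510 regions of highest score, the median inside gene bodies was lower by 4.5, which did not pass after adjustment (permutation p = 0.0402, adjusted p = 0.0803).

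Because Zscan4 is known for its role at telomeres, the distal ends of the chromosomes were examined. The last 5 Mb held 206 of 4927 regions (4.18%, 95% Wilson interval 3.66 to 4.78%), against 190 expected, a ratio of 1.08 that did not pass the test (two-sided permutation p = 0.254). In the last 1 Mb the ratio was 1.49 and passed it (permutation p = 0.00999), as did the ratio of 1.39 in the last 5 Mb among the 1252 regions of highest score (permutation p = 0.00799). On chromosomes 2, 7, 12, 14, 18 and X the last listed region lay beyond the last gene and itself set the chromosome end. Such a region was inside these windows by construction wherever the set of regions held it. In all, 57 regions lay in the last 1 Mb, and 64 of the 1252 highest lay in the last 5 Mb. No test was run without these last regions, so these passes do not by themselves show an excess at chromosome ends.

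The fourth question was whether genes of the 2-cell-like state, of pluripotency or of chromatin regulation had FLAG-Zscan4 regions more often than genes of like span. A gene counted when a region lay in its body or within 10 kb on either side. None of the 11 fixed lists passed the permutation test after adjustment over the lists, and 1 list had an unadjusted p below 0.05. In the Zscan4 family, 1 of 6 genes had a region (0.368 expected), which was Zscan4c itself (chromosome 7, 11009496 to 11009964, score 102). The transfected plasmid carries the coding sequence of the same gene, and reads from the plasmid and from the endogenous locus were not separated here. In the 2-cell-like list, 6 of 54 genes had a region (3.89 expected, permutation p = 0.381). These were Duxf3 (chromosome 10, 58230936 to 58231540, score 157), which encodes the transcription factor Dux that drives the 2-cell programme, Zscan4c, Obox6 (2 regions, highest score 69), Calcoco2 (49), Sp110 (3 regions, 36) and Pramel19 (13).

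Among naive pluripotency genes, 7 of 31 had a region against 2.99 expected (permutation p = 0.046, adjusted p = 0.506). They were the nuclear receptor gene Nr5a2 (chromosome 1, 136918025 to 136918359, score 47), Klf5 and Gdf3 (23 each), Dppa3 and Il6st (18 each), the leukaemia inhibitory factor receptor gene Lifr (13) and Dppa2 (10), all but Nr5a2 below the median score of 33. When a gene counted within 50 kb, this was the list that passed, with 16 of 31 genes against 7.57 expected (permutation adjusted p = 0.0198), among them Prdm14 (3 regions, highest score 66), Tdgf1 (60), Klf5 (3 regions, 46) and Zfp42 (43). Neighbouring members can share a region, as Gdf3 and Dppa3 and also Dppa2 and Dppa4 did for their highest, so that the 16 genes had 14 different highest regions. Rotation of the regions along each chromosome, added after this was seen, keeps such neighbours together and gave 5.87 genes (permutation adjusted p = 0.0088), while of the housekeeping genes 7 of 18 had a region within 50 kb against 2.97 (permutation p = 0.0446, adjusted p = 0.245). For 11 of the 16 genes the highest region had a score below the median of 33, and the list did not pass without the weaker regions, a check added after the result was seen: 5 genes had one of the 2510 regions of highest score within 50 kb, a ratio of 1.2, and 2 had one of the 1252 highest, a ratio of 1.03 (permutation adjusted p = 1 for both). Pou5f1, Sox2 and Nanog, the core pluripotency factors, had no listed region within 50 kb.

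The other lists stood near the number drawn at random. Of telomere and homologous recombination genes, 3 of 32 had a region (4.02 expected), namely the meiotic gene Hormad1 (score 66), the histone H3.3 chaperone gene Daxx (40) and the meiotic recombinase gene Dmc1 (14). Of enzymes of histone acetylation, deacetylation and H3K4 methylation, 5 of 37 had one (5.98 expected), with the deacetylase gene Hdac9 highest (chromosome 12, 34139459 to 34140552, score 182), and others at Kat6b (39), Hdac4 (32) and Kat2b (23). Retroelement silencing genes gave 5 of 25 (3.05 expected), with Atf7ip (42), Pphln1 (40), Trim28, which encodes the corepressor recruited by KRAB zinc finger proteins (33), Zfp809 (27) and Dppa2 (10). Of DNA methylation genes, 1 of 13 had a region (2.05 expected), which was Zfp57, an imprinting regulator (42). Germ layer regulators gave 1 of 22 (1.72 expected), with Mixl1 (10), and trophoblast genes 3 of 16 (1.33 expected), with Prl3d1 (28), Prl2c2 (14) and Tead4 (13). Of the fibroblast markers, 2 of 15 had a region (1.66 expected), S100a4 (28) and Pdgfrb (23), and of the housekeeping genes 2 of 18 (1.14 expected), among them Polr2a (23).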

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

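The tests of high-copy repeats and of the last regions of chromosomes were chosen after the result was seen, and the test of inward spread was chosen before.

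A signal stood outside the gene and placement comparisons, which covered chromosomes only: 40 FLAG-Zscan4 regions lay on unplaced scaffolds, where the gene table used gives no coordinates. Of these, 26 lay on JH584304.1, with scores up to 7195, and 1 on GL456389.1 had a score of 987. No input values were used here, so the level in the control library was not compared.

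Very high scores also stood at the ends of assembled chromosomes. The last listed region was among the 50 highest on 5 of 20 chromosomes, namely 12 (score 3658), 14 (2818), 7 (1892), 18 (1331) and 2 (872), and each lay beyond the last annotated gene of its chromosome. A region drawn at random from each chromosome gave 0.143 such chromosomes on average and 3 at most (one-sided permutation p = 1.00e-05, the smallest that 100000 draws can give). Reads of high-copy repeats that pile up on short assembled stretches are a candidate explanation that stays open. That 16 of the 50 highest regions lay on unplaced scaffolds had been seen before this explanation was framed, and it does not test the chromosome ends themselves. A candidate biological explanation, binding that spreads inward from chromosome ends, also stays open: in the last 1 Mb, without each chromosome's last region, the median score was 39 over 35 regions against 33 elsewhere, a difference of 6 (two-sided permutation p = 0.215). Binding of FLAG-Zscan4 to telomeric repeats themselves was not tested, because repeat sequence and input signal were not used here.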

How the results depend on the processing

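Rotation (of lists within 50 kb too), score filters within 50 kb, leaving out dense windows and leaving out chromosomes 1 and 8 were added after the data were seen, and the other settings were fixed before. Of 98 alternative values, 72 stayed on their side of the threshold with no turn of direction or, for counts with no test, stayed close to the main count. The ratio at gene ends, 1.12, passed the test within 5 kb (1.23), with any overlap (1.12) and on autosomes and the X chromosome (1.12). It kept its size but no longer passed with the 2510 regions of highest score (1.12), with regions merged within 1 kb (1.12) and by rotation (1.12), and it was smaller and did not pass without dense windows (1.06) and without chromosomes 1 and 8 (1.07). It turned to 0.966 with the 1252 regions of highest score and to 0.851 at protein-coding genes. The excess of neighbours stayed past the threshold in 6 of 6 alternatives, from 1.44 to 10.9 times the expected number. Gene bodies fell to 1.00 in the 1252 regions. The distal ends passed with the 1252 regions (1.39) and within 1 Mb (1.49), where the last listed region of some chromosomes lay in the window by construction. The number of chromosomes that departed from their share was 9 with 2510 regions and 8 with 1252, against 5. On autosomes and the X chromosome alone it was 5 as well. There chromosomes 3 and 18 fell below their share in place of the Y and mitochondrial calls. Chromosome 1 was lost with 1252 (1.28). The exact binomial test behind these counts takes regions as independent, so a local cluster can add a call. Within 50 kb, 1 list passed, naive pluripotency, at 2.11 times the expected number, and by rotation 1 list passed too, the same one, at 2.73. Within 50 kb no list passed with 2510 or 1252 regions, where naive pluripotency stood at 1.2 and 1.03. In the 10 kb setting, that list turned to 0.69 with 2510 regions and to 0 with 1252. The 2-cell-like list turned to 0.943 in Fisher's exact test against protein-coding genes and to 0.964 within 50 kb with 2510 regions. The score difference for gene bodies was -4.5 with 2510 regions (permutation p = 0.0402, adjusted p = 0.0803) and -9 with 1252 (permutation p = 0.0561, adjusted p = 0.112), and for gene ends it turned to -4 with 2510 and to -2 with 1252. The cause was not tested for these changes.

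No paired analysis was possible because each group held 1 sample. The planned results on GC content, masked repeats, the TGCACAC motif, CA/TG microsatellites, k-mers and repeat families were not run, nor were their alternatives and the repeat-masked version of regions per chromosome, since genome sequence was not used here. Transcription start sites were replaced by gene ends. The read depth is unknown, so how far it limited the number of regions was not assessed.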

Other observations

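The family scan, the tests of chromosomes 8 and 1, the chromosome 4 cluster test for Zfp genes and the count of 1 gene per group were chosen after the result was seen, while the tests of Zfp gene span and of gene-dense surroundings were chosen before.

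Genes of the Zfp series, which encode zinc finger proteins, had FLAG-Zscan4 regions more often than rotation of the regions gave. A region lay in the body or within 10 kb of 72 of 416 Zfp genes, against 34.5 when the regions were rotated along their chromosomes, a ratio of 2.09 (permutation p = 2.00e-04, the smallest that 10000 rotations can give, adjusted p = 0.0146 over 73 symbol families). Of the 73 families, 1 passed. Higher ratios that did not pass were those of Snord (3.80, 13 of 94 genes), Snora (2.91), Prss (2.47), Klhl (2.29), Cep (2.29), Cldn (2.24) and Usp (2.12), which have fewer genes. Olfactory receptor genes stood on the other side, with 31 of 1427 against 53.8 expected, and did not pass (permutation p = 0.0314, adjusted p = 0.382). On chromosome 4 between 145 and 148 Mb, 12 of 16 Zfp genes had a region, and that stretch held 50 regions in all. Elsewhere 60 of 400 did, with 21 of 94 on chromosome 7, 8 of 39 on chromosome 13 and 5 of 47 on chromosome 17, and with 2 of 30 on chromosome 2, 2 of 27 on chromosome 8 and 2 of 23 on chromosome 11. The highest scores near Zfp genes were at Zfp697 on chromosome 3 (98386566 to 98387151, score 919), Zfp993 (248), Zfp982 (238), Zfp473 on chromosome 7 (44738556 to 44739186, score 213) and Zfp978 (209). These genes other than Zfp993 and Zfp978 were chosen after their values were seen.

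Of the explanations for the Zfp pattern, the tables argued against 3 as the sole cause. Each was tested by itself and not together with the others, so a part played by any of them was not excluded. Without the chromosome 4 cluster the ratio over rotations was still 1.85 (permutation p = 0.001998), so that cluster alone did not account for it. Against random genes of like span the ratio was 1.63 (44.2 genes expected), and against genes with as many neighbours within 500 kb it was 1.82 (39.5 expected), each with a permutation p of 2.00e-04, the smallest those draws can give. Neighbouring Zfp genes can share a region, and the 72 genes had 66 different highest regions. With 1 gene kept per group of overlapping windows, 56 of 303 genes had a region, a ratio of 1.66 for like span (permutation p = 4.00e-04) and of 1.85 for as many neighbours (permutation p = 2.00e-04). Reads shared between near-identical Zfp copies, and immunoprecipitated repeats within the clusters, stay open and were not tested. A contact of FLAG-Zscan4 with Zfp genes may therefore be offered as a hypothesis only.

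Chromosomes 8 and 1 carried more regions per Mb than the other autosomes. Without the dense 1 Mb windows the smaller of the 2 ratios to the other autosomes was 1.39 and the larger 1.56, so dense windows were not the whole cause, and regions per gene gave ratios of 1.69 and 1.97, which argued against gene density. A candidate explanation is an extra copy of these chromosomes in the picked clone, since trisomy of chromosomes 8 and 1 is a known event in mouse ES cell culture. The lower quartile of 10 Mb windows was 22.5 regions on chromosome 8 and 18 on chromosome 1 against 13 on the other autosomes, ratios of 1.73 and 1.385. Of the windows, 8 of 11 on chromosome 8 and 14 of 18 on chromosome 1 lay above the others' median of 16.5, so the excess was not seen in every window, and the explanation stays open. The number of listed regions need not scale with copy number, and whether the input entered the peak calls is not given in the sources used here. Copy number was not measured, and no biological explanation was tested.

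The X chromosome, present as 1 copy in male cells, had a ratio of 0.515 to the other autosomes. Its deficit was larger among regions with a score below the median (0.301) than among those at or above it (0.748). On chromosomes 8 and 1 the departure was larger among regions at or above the median (2.26 and 1.56) than below it (1.82 and 1.28). These differences were not tested. On chromosome 8, the densest 1 Mb window alone held 76 regions (16.5% of the chromosome's regions) with a median score of 105. The split by score was not repeated without dense windows, so the difference on chromosome 8 may rest on that window.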
